A study of Mus musculus with 11 samples.

How the data were processed

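RNA of mouse RAW cells with a control hairpin or a hairpin against GIV, without LPS or after 5 h of LPS at 100 ng/ml, was sequenced as ribosome-depleted stranded total RNA in paired reads of 100 bases, per the labels. The labels list 11 samples, and 1 of them, control cells with LPS replicate 3, has no column and is not analysed here. The authors made the log2 values, which are log2(TPM + 1) per gene, with kallisto 0.45.0 on the build GRCm38, per the submitters' processing notes. The deposited table holds 52143 genes in 10 libraries, and 2 to the power of each value, minus 1, adds up to 1000000 per library. The annotation release and the way transcripts were summed to genes are not stated. TPM values keep no read total, so depth per library and the counting precision it gives are unknown. No 2 of the 45 pairs of libraries were identical. Gene positions, biotypes, lengths and GC content came from GENCODE M21, and 51262 genes (98.3%) had a length and GC content. A reference list of gene names held 51250 of the gene identifiers. Repeated symbols (718) were kept as separate genes by identifier.

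Groups, comparisons, filter, tests, 31 gene lists and the alternatives of the 10-library fit, except removal of the GC trend, were fixed before the data were examined. The lists cover inflammatory signalling and effectors, macrophage states, metabolism, cell division, stress, GIV-related signalling, other cell types and library composition. The gene-level test was limma 3.58.1 in R 4.3.3, with 1 model of the 4 groups and moderated variances with a mean-variance trend. Genes with log2(TPM + 1) of at least 1 in at least 2 libraries were tested, which gave 13919 genes with 10 libraries and 13711 with 9. Residual degrees of freedom were 6 and 5. P-values were adjusted by Benjamini-Hochberg within each comparison, with a threshold of 0.05. The 5 comparisons were LPS in control cells, LPS in depleted cells, depletion without LPS, depletion with LPS, and the difference between the 2 LPS responses. Control cells with LPS are a lone library that is assumed to vary like the other groups.

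The fit with 9 libraries leaves out the library labelled control replicate 2 without LPS. Leaving out each library was planned, but giving this fit beside that with 10 libraries was chosen after its composition was seen. The plan named all 11 samples, and the 10-library fit follows it without the sample that has no column. Lists with at least 3 tested members were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. List members were also adjusted over the list alone. The Ccdc88a level was tested by an exact two-sided permutation of the lines within each time. Named genes are Ccdc88a, 12 genes of macrophage activation, the 10 largest called changes in each direction, and for each list the 4 called members with the largest change, or the 2 with the highest mean where none was called. The largest changes needed a log2 group mean of at least 3, groups that did not overlap (not asked for the difference) and a symbol held by a single gene.

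Alternatives were the set number as a block, no filter and a stricter filter (log2 of at least 3 in at least 2 libraries), a pseudocount of 0.1, TMM scaling computed from TPM (trims of 30% and 5%), quantile normalization, rescaling without mitochondrial and the 100 most abundant genes, removal of each library's GC trend (lowess span 0.3), eBayes without the trend and with robust=TRUE, only the 2 groups compared, only sets 2 and 3, and leaving out each library. The 9-library fit was also run under each. On simulated data in which 200 genes were changed, the 9-library fit recovered 49.3% of log2 changes of 1 for LPS in control cells, 85.1% for LPS in depleted cells, 67.2% for depletion without LPS, 65.7% with LPS and 50.7% for the difference. The 10-library fit recovered 0 at that size, and at most 18.2% at a log2 change of 2. Of the calls in the 9-library fit 2.48% to 7.3% were wrong. The simulation gave each gene the same spread in every library and changed fewer genes than the LPS comparisons called. These shares are therefore not the power in these data. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.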

Results

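Total RNA of mouse RAW cells, a macrophage-type line, was sequenced to ask how Girdin (GIV) shapes the response to lipopolysaccharide (LPS), the bacterial cell wall component that Toll-like receptor 4 senses. Cells carrying a short hairpin RNA against GIV were compared with control hairpin cells, either without LPS or after 5 h of LPS at 100 ng/ml. The labels describe 11 samples, and 10 of them have a column in the table of transcript levels. These were 3 control libraries without LPS, 1 control library with LPS (replicate 2), 3 GIV-depleted libraries without LPS and 3 GIV-depleted libraries with LPS. Replicate 3 of the control cells with LPS was not analysed here. Levels are TPM values, which add up to 1000000 in each library, so the sequencing depth of each library is unknown. Log2 changes are of TPM + 1, so they are small for transcripts near 0. Between 19795 and 21678 genes had a value above 0. The labels do not say whether replicates were separate cultures, so every p-value measures only the spread between these samples.

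Replicate 2 of the control cells without LPS stood apart in composition. Mir6236, an annotated microRNA gene, took 57.8% of its TPM, against 3.79% to 8.78% in the other 9 libraries. The 6 most abundant small and ribosomal RNA genes, Mir6236 among them, took 87.4%, against 10.4% to 18.1%. Genes annotated as ribosomal RNA took 3.54%, against 0.241% to 0.559%. Protein-coding genes took 7.80% of its TPM, against 73.9% to 81.5%, and mitochondrial genes took 0.263%, against 3.61% to 8.32%. Its Spearman correlation with the other libraries without LPS was 0.713 to 0.721 across genes, against 0.963 to 0.982 for the other libraries with those of their own time. Across 3769 abundant coding genes its level lay at a median of -3.06 log2 units from the other 2 control libraries. The 81 ribosomal protein genes lay at -5.42, while the nuclear RNA Malat1 lay 2.14 above. Each comparison is therefore given with all 10 libraries and without this library. The plan named all 11 samples, so the 10-library fit is the plan short of the control sample with no column. The choice to lead with 9 libraries was made after seeing the data. Named genes are described from the 9-library fit unless the 10-library fit is named.

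**Figure D1:**
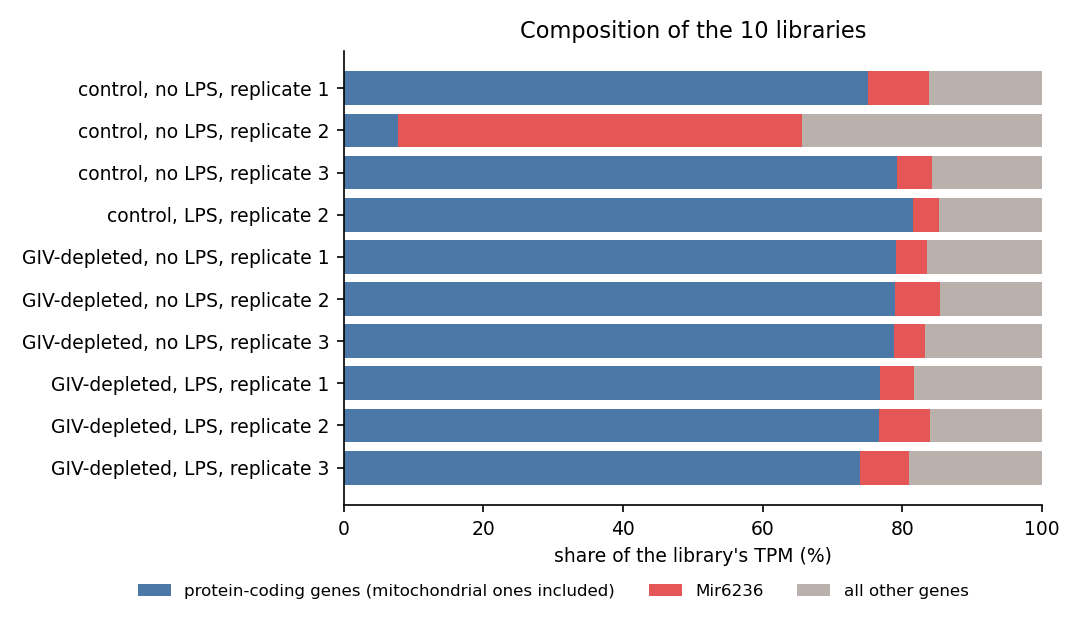
Share of each library's TPM, in percent on the horizontal axis, taken by protein-coding genes, by Mir6236 and by all other genes, for the 10 libraries on the vertical axis. Protein-coding genes hold 7.80% of the TPM of the library labelled control replicate 2 without LPS and 73.9% to 81.5% of that of the other 9 libraries.

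Ccdc88a (ENSMUSG00000032740, GRCm38 chromosome 11, 29373658 to 29510808, plus strand) encodes GIV, an actin-binding modulator of trimeric G proteins, and was the transcript targeted. Without LPS it was at 10.0, 1.18 and 7.69 TPM in control replicates 1, 2 and 3, and at 6.93, 5.31 and 5.58 TPM in the depleted ones. With LPS it was at 5.77 TPM in the control library and at 3.08, 2.62 and 3.39 TPM in the depleted libraries. Without the library labelled control replicate 2, the depleted mean was 67.2% of the control mean without LPS and 52.5% with LPS. The log2 differences were -0.50 ± 0.15 (SE, limma adjusted p = 0.232) and -0.75 ± 0.19 (adjusted p = 0.0681), neither past the threshold over all genes. Leaving out a further library gave -0.67 to -0.33 without LPS and -0.82 to -0.68 with LPS. Pooled over both times, the mean difference of -0.63 log2 units was larger than under every other assignment in an exact two-sided permutation test within time (p = 0.025, 1 of 40 assignments, the smallest p it allows). With all 10 libraries the difference without LPS was 0.22, below the median of all genes of 0.64, and it turned to -0.38 with TMM scaling, -0.23 with quantile normalization and -0.48 with rescaling. The pooled permutation test then had p = 0.588 (47 of 80 assignments). The library labelled control replicate 2 lay below every depleted library in TPM of this transcript, but its coding genes were low as a whole, so this does not bear on its label.

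**Figure D2:**
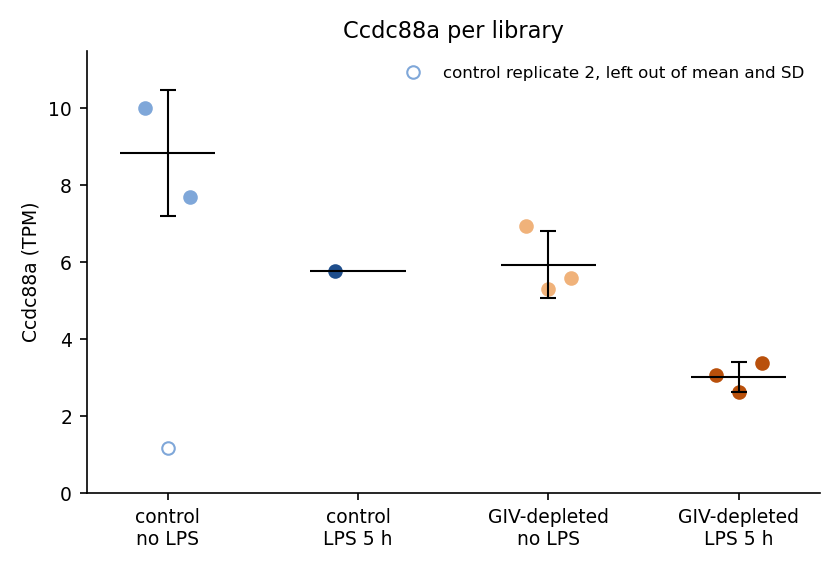
Ccdc88a in TPM on the vertical axis for each library (points) of the 4 groups on the horizontal axis, with the mean and SD of each group except the library labelled control replicate 2 without LPS, drawn open at 1.18 TPM. The remaining control libraries lie at 10.0 and 7.69 TPM without LPS and 5.77 TPM with LPS, above the depleted libraries of the same time.

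The response of control cells to LPS shows which transcripts normally change within 5 h. Inflammatory transcripts that were close to absent rose to rank among the abundant ones. Il1b, the secreted fever cytokine interleukin 1 beta, went from 0.497 ± 0.209 TPM (SD, n = 2) to 3939 TPM, a log2 change of 11.37 ± 0.25 (SE). The neutrophil growth factor Csf3 rose by 10.94 ± 0.15, the neutrophil-attracting chemokine Cxcl2 by 10.12 ± 0.20 and the acute-phase gene Saa3 by 9.88 ± 0.33. Genes of cell division fell at the same time, such as the cyclin Ccne2 by -3.92 ± 0.25 and Rrm2, a subunit of the enzyme that makes DNA building blocks, by -3.52 ± 0.09. The largest fall among named genes was in Gpr183, an oxysterol receptor that guides cell migration, from 43.3 ± 2.83 TPM (SD, n = 2) to 0.471 TPM, a change of -4.91.

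All 16 tested proinflammatory cytokines of 19 listed rose in control cells, as did all 15 tested chemokines of 18 listed. The other listed members were too low to be tested. All 37 interferon-stimulated genes rose too, and the same counts rose when adjusted over the list alone. Among them Il1a rose by 9.24, Il27 by 8.67, Il6 by 7.51 and Tnf by 4.81, the chemokine Ccl5 by 9.92 and Ccl2 by 7.57. The antiviral genes Rsad2, Gbp5 and Gbp2 rose by 7.45, 7.22 and 7.11. Of 21 classical activation effectors 20 rose, again 20 adjusted over the list alone. They include Nos2, which makes nitric oxide (8.60), Ptgs2, which makes prostaglandin precursors (8.57), and Acod1, which makes itaconate (8.68). Camera set tests gave adjusted p of 1.49e-19 for the cytokines, 7.13e-19 for the chemokines, 4.00e-38 for the interferon list and 5.42e-20 for the effectors. With an estimated correlation the adjusted p were 0.0231, 0.00531, 0.0612 and 0.0231, so the interferon list no longer passed.

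Brakes on inflammation rose as well in control cells. Of 21 feedback regulators 18 rose and 3 fell, the same adjusted over the list alone, with the cytokine signalling inhibitor Socs3 at 7.02, the anti-inflammatory cytokine Il10 at 6.60 and the receptor antagonist Il1rn at 5.16. The list of 14 NF-kB subunits and inhibitors mixes activating and restraining genes, so it is not a list of brakes alone. Of these 12 rose and 1 fell, the same adjusted over the list alone, led by Nfkbiz (5.11) and the ubiquitin editor Tnfaip3 (4.56). The camera adjusted p were 2.99e-15 and 1.07e-10, each with adjusted p = 0.0792 with an estimated correlation. Of 21 genes of the receptor and its proximal signalling 9 rose and 6 fell (9 to 14 and 4 to 6 over 4 scalings, the main 1 and 3 others), also adjusted over the list alone (camera adjusted p = 0.00226, 0.407 with an estimated correlation). Tlr4 itself changed by -1.19 ± 0.22 while its adaptor Myd88 rose by 1.69 and the kinase Ikbke by 3.57. All 31 cell cycle and DNA replication genes fell, 31 adjusted over the list alone, and their median lay -1.90 log2 units from that of all genes (camera adjusted p = 7.42e-13, adjusted p = 0.0792 with an estimated correlation).

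Smaller shifts reached other groups in control cells. Of 15 antigen presentation genes 11 rose and 4 did not pass, 11 adjusted over the list alone, led by the peptide transporter Tap1 (3.35) (camera adjusted p = 3.57e-08, adjusted p = 0.164 with an estimated correlation). Of 14 inflammasome genes 9 rose and 3 fell, 10 and 3 adjusted over the list alone, with the sensor Nlrp3 at 3.57 and Gsdme, a pore protein, at -1.97 (camera adjusted p = 1.73e-05, adjusted p = 0.0612 with an estimated correlation). Of 14 matrix protease and remodelling genes 8 rose and 4 fell, also adjusted over the list alone, such as the protease inhibitor Timp1 at 4.98 (camera adjusted p = 1.97e-04, adjusted p = 0.0577 with an estimated correlation). Serpinb2 of that list was at 89.6 TPM with LPS and is listed at 0 without. Of 15 alternative activation markers 6 rose and 3 fell, also adjusted over the list alone, with the transcription factor Myc at 3.37 and the lipid sensor Pparg at -1.56 (camera adjusted p = 0.0161, adjusted p = 0.192 with an estimated correlation). Of 30 nuclear oxidative phosphorylation genes 24 fell and none rose, 25 adjusted over the list alone (camera adjusted p = 0.00462, adjusted p = 0.527 with an estimated correlation), though over the 4 scalings their median ranged from -0.57 to 0.03, with 0 to 5 higher and 4 to 29 lower.

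In control cells limma called 8075 of 13711 genes without the library labelled control replicate 2, 2025 higher and 6050 lower, and 481 of 13919 with all 10 libraries, 428 higher and 53 lower. All 480 of the latter that were tested in both fits were called in the same direction without that library. The split between higher and lower depended on the scaling, with a median of all genes of -0.40. With 9 libraries TMM scaling, which moved that median by 0.40, gave 3902 higher and 3422 lower and quantile normalization 2987 and 4266, while rescaling kept the excess of lower genes at 2010 and 6571. With 10 libraries TMM gave 1736 and 1525, quantile normalization 1333 and 1327, and rescaling without mitochondrial and the 100 most abundant genes 1071 and 3310. The LPS group is a lone library here, assumed to vary like the other groups, and with only the 2 groups compared 2859 genes were called, 1036 higher and 1823 lower.

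GIV-depleted cells answered the question of what LPS does without normal GIV levels, with 3 libraries at each time. The 10 largest rises among named genes were in the same 10 genes as in control cells, in another order. Il1b went from 0.718 ± 0.399 TPM (SD, n = 3) to 7005 ± 45.7 TPM (SD, n = 3), a log2 change of 12.02 ± 0.16 (SE). Il1a rose by 10.34 ± 0.07, Csf3 by 10.22 ± 0.10, Saa3 by 10.08 ± 0.22 and the T cell chemokine Ccl5 by 9.71 ± 0.16. The largest falls among named genes were in Ttc39aos1, a noncoding RNA, at -5.36 ± 0.20, the vessel growth factor Angpt2 at -4.81 ± 0.09, Gpr183 at -4.63 ± 0.15 and Rasgrp3, an activator of Ras, at -4.52 ± 0.06.

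Again all 16 tested cytokines rose in depleted cells, with all 15 tested chemokines, all 37 interferon-stimulated genes and 20 of 21 classical effectors. Adjusted over the list alone the counts were 16, 15, 37 and 21. Tnf rose by 4.02, Il6 by 8.05, Nos2 by 8.47, Ptgs2 by 8.57, Il10 by 7.25 and the interferon target Gbp3 by 7.46. Ccl22, which attracts regulatory T cells, rose by 8.22. Camera gave adjusted p of 2.07e-19, 1.38e-18, 4.68e-38 and 2.06e-21 for the 4 lists, and with an estimated correlation adjusted p of 0.0235, 0.00552, 0.0614 and 0.0211. Of the matrix protease and remodelling genes 8 rose and 4 fell, also adjusted over the list alone, such as Timp1 at 6.06 (camera adjusted p = 2.15e-05, adjusted p = 0.0345 with an estimated correlation). All 31 cell cycle genes fell, also adjusted over the list alone, with Ccne2 at -4.04 and the mitotic cyclin Ccna2 at -3.47 (camera adjusted p = 1.10e-09, adjusted p = 0.132 with an estimated correlation).

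Several lipid synthesis genes fell in depleted cells, though the balance of the list depended on scaling. Of 21 cholesterol biosynthesis genes 16 fell and none rose, 16 adjusted over the list alone, with the sterol reductase Dhcr7 at -3.18 and the decarboxylase Mvd at -1.57 (camera adjusted p = 0.0493, adjusted p = 0.430 with an estimated correlation). Their median was -0.63 and reached 0.04 under another scaling, with 0 to 8 higher and 9 to 16 lower over the 4 scalings. The desaturase Scd2 changed by -3.75 and the fatty acid synthase Fasn by -1.96, within a lipid handling list of 18 in which 11 fell and 4 rose (9 to 11 and 4 to 8 over the 4 scalings), also adjusted over the list alone (camera adjusted p = 0.845). Of 13 mitochondrially encoded transcripts 12 fell, also adjusted over the list alone, such as mt-Cytb at -1.24, but over the 4 scalings 2 to 12 fell, and camera gave adjusted p = 0.225. Of 21 phagocytic and adhesion receptors 10 rose and 9 fell, also adjusted over the list alone (camera adjusted p = 0.00277, adjusted p = 0.429 with an estimated correlation). The antibody receptors Fcgr1 and Fcgr4 rose by 4.87 and 4.05 while Csf1r, the receptor for the macrophage growth factor, changed by -3.21.

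For depleted cells limma called 10349 of 13711 genes without the library labelled control replicate 2, 2161 higher and 8188 lower. With all 10 libraries it called 2236 of 13919, 785 higher and 1451 lower, and all 2236 were also called in the other fit. Their direction there was fixed, since the library left out is a control and the depleted libraries are the same. The fits differ here only in the shared variances and the genes tested. With 9 libraries TMM scaling, which moved the median of all genes by 0.55, gave 4737 higher and 4467 lower, quantile normalization gave 3768 and 5522, and rescaling gave 2444 and 7715. With 10 libraries TMM gave 2554 and 2524, rescaling 1551 and 4850, no filter 1037 and 1256, only the 2 groups compared 2184 and 8256, and only sets 2 and 3 turned the balance to 267 and 49. Leaving out depleted replicates 1, 2 or 3 at rest gave 574 and 620, 558 and 552, or 546 and 535, and leaving out those with LPS gave 583 and 544, 568 and 559, or 587 and 489. The control and depleted responses, which share no library, had a Pearson correlation of 0.894 and a Spearman correlation of 0.853 across 13711 genes, which are not independent replicates. The slope of the depleted on the control response was 0.912. Genes called in both numbered 1772 higher and 5887 lower, where independent lists would share 319 and 3613, and 31 were called in opposite directions.

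GIV depletion without LPS asks how the cells differed at rest. Several genes of bone-resorbing cells were higher in depleted cells, 5 of 8 without the library labelled control replicate 2. The list then had a camera adjusted p = 0.0988 with an estimated correlation. With all 10 libraries 0 of 8 were called, though the list's median still lay 0.86 log2 units above that of all genes (camera adjusted p = 5.85e-05, 0.993 with an estimated correlation). Acp5, the tartrate-resistant phosphatase that stains osteoclasts, was at 31.5 ± 2.98 TPM (SD, n = 3) against 10.1 ± 0.345 TPM (SD, n = 2) in controls, a log2 difference of 1.54 ± 0.10 (SE). The proton pump subunit Atp6v0d2 rose by 1.48 ± 0.07, the osteoclast transcription factor Nfatc1 by 1.13 ± 0.10, the fusion receptor Dcstamp by 0.89 ± 0.08 and the gelatinase Mmp9 by 0.89 ± 0.09. The largest rise among named genes was in Rgs16, which shortens signalling by trimeric G proteins, from 2.33 ± 0.294 TPM (SD, n = 2) to 13.2 ± 2.21 TPM (SD, n = 3), or 2.08 ± 0.13. The largest falls among named genes were in Rnase4, a secreted ribonuclease (-1.60 ± 0.13), the monocyte chemokine Ccl2 (-1.53 ± 0.15) and the Langerhans cell lectin Cd207 (-1.37 ± 0.10).

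Of 8 osteoclast differentiation genes 5 rose at rest and none fell, 6 adjusted over the list alone, and the list's median lay 0.86 log2 units above that of all genes (camera adjusted p = 3.89e-11, adjusted p = 0.0988 with an estimated correlation). Of 21 phagocytic and adhesion receptors 5 fell and 1 rose, 8 and 2 adjusted over the list alone (camera adjusted p = 0.00110, adjusted p = 0.718 with an estimated correlation). The antibody receptors Fcgr3 and Fcgr1 changed by -1.18 and -0.73 and the macrophage marker Adgre1 by -0.67, while the integrin Itgax rose by 0.85. The scavenger receptor genes Msr1 and Cd36 were at -0.86 and -0.97 and the growth factor Igf1 at -1.17. Of 23 lysosomal genes 1 fell (1 to 6 over the 4 scalings), the protease Ctsl at -0.67, and 7 fell and 1 rose adjusted over the list alone (camera adjusted p = 3.45e-05, adjusted p = 0.718 with an estimated correlation). Of 37 interferon-stimulated genes 1 fell, Oasl2 at -0.61, also adjusted over the list alone (camera adjusted p = 2.11e-05, adjusted p = 0.718 with an estimated correlation).

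A few inflammatory genes passed at rest. Of 16 cytokines 1 rose, also adjusted over the list alone, of 15 chemokines 1 fell, 2 adjusted over the list alone, and of 21 classical effectors 1 rose and 2 fell, 3 and 5 adjusted over the list alone (camera adjusted p = 0.909, 0.897 and 0.241). Tnf, Il6 and Nos2 did not pass: Tnf differed by 0.09 ± 0.07, Il6 by -0.03 ± 0.10 and Nos2 by 0.07 ± 0.09, and none of the genes of the NF-kB, receptor signalling, glycolysis, oxidative phosphorylation, cholesterol and cell cycle lists was called. Il10 was lower, at -0.56 ± 0.09. Limma called 167 genes without the library labelled control replicate 2, 67 higher and 100 lower. With all 10 libraries limma called 0 genes, with 408 at an unadjusted p under 0.05, and Fcgr3, Igf1, Msr1, Cd36, Fcgr1, Adgre1, Ctsl and Oasl2 then had differences of 0.18, 0.26, 0.44, 0.23, 0.12, 0.44, 0.76 and 0.02, all but Ctsl below the median of all genes of 0.64 in that fit. Leaving out a further library gave 79 genes without control replicate 1, 58 without control replicate 3, 105, 76 and 84 without depleted replicates 1, 2 and 3 of this time, and 103 and 106 without depleted replicates 1 and 3 with LPS. TMM scaling gave 253, rescaling 277, quantile normalization 306, the set number as a block 58, only the 2 groups compared 16 and only sets 2 and 3 gave 0.

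**Figure D3:**
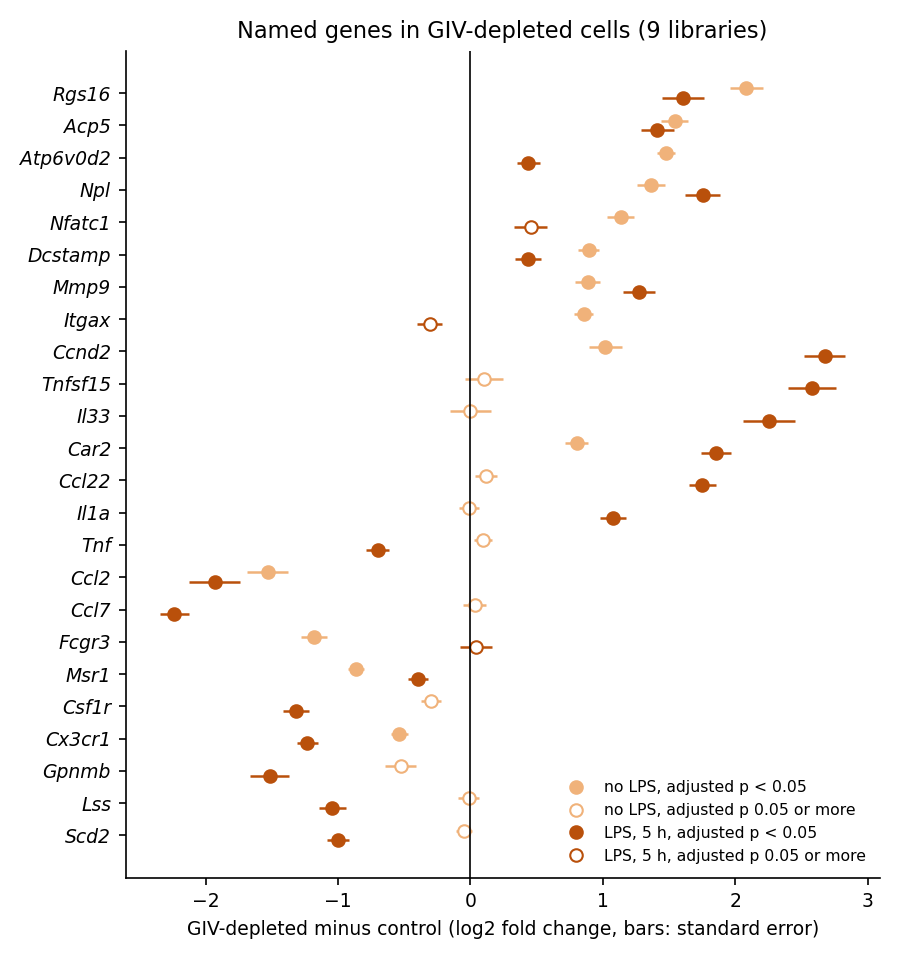
Log2 difference of GIV-depleted from control cells, with its standard error, on the horizontal axis for 24 named genes on the vertical axis, without LPS (light) and after 5 h of LPS (dark), from 9 libraries, filled where the adjusted p passed. Acp5 lies at 1.54 and 1.41, Ccl2 at -1.53 and -1.93, and Ccnd2 at 1.02 and 2.68.

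GIV depletion with LPS asks how the stimulated cells differed, against the lone control library with LPS. Depleted cells held more of several cytokine transcripts and of a cyclin, while other cell cycle genes were lower or not called. Ccnd2, a cyclin of the first phase of the cell cycle, was at 11.3 ± 0.405 TPM (SD, n = 3) against 0.928 TPM, a log2 difference of 2.68 ± 0.16 (SE). The cytokine Tnfsf15 rose by 2.58 ± 0.18, the alarm cytokine Il33 by 2.25 ± 0.20, carbonic anhydrase Car2 by 1.85 ± 0.11, the chemokine Ccl22 by 1.75 ± 0.10 and the cytokine Il1a by 1.08 ± 0.10. Of 16 cytokines 2 rose and 1 fell, 4 and 3 adjusted over the list alone (camera adjusted p = 0.0247, adjusted p = 0.638 with an estimated correlation). Over 4 scalings, the main 1 and 3 others, 2 to 4 of them rose and 1 fell. The monocyte-attracting chemokines Ccl7 and Ccl2 were lower, with Ccl7 at 26.4 ± 0.835 TPM (SD, n = 3) against 128 TPM (-2.23 ± 0.11) and Ccl2 at 477 ± 18.5 TPM (SD, n = 3) against 1820 TPM (-1.93 ± 0.19). Tnf was lower, at -0.70 ± 0.09, at 1299 ± 90.4 TPM (SD, n = 3) against 2108 TPM.

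Further genes higher in depleted cells with LPS were Hamp, the iron hormone hepcidin (1.98), Npl, a sialic acid enzyme (1.75), the cytoskeletal regulator Rnd1 (1.70) and the checkpoint receptor Pdcd1 (1.62). Bcl2a1a, a survival gene, was 1.94 higher, but it has near-identical copies, so its share of reads is uncertain. The largest fall among named genes was in Fam20c, a kinase of secreted proteins (-2.43 ± 0.21). Lhfpl2 (-1.94), the clock repressor Bhlhe41 (-1.83), the membrane protein gene Tm4sf19 (-1.80), the basement membrane collagen Col18a1 (-1.80) and the membrane glycoprotein Gpnmb (-1.52) were also lower. Of 21 phagocytic and adhesion receptors 5 fell and 1 rose, 11 and 2 adjusted over the list alone (camera adjusted p = 0.0229, adjusted p = 0.638 with an estimated correlation). Csf1r was at 43.0 ± 1.43 TPM (SD, n = 3) against 109 TPM (-1.32) and the fractalkine receptor Cx3cr1 at -1.23.

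Of 21 cholesterol biosynthesis genes 10 fell in the stimulated depleted cells (6 to 10 over the 4 scalings) and none rose, 20 adjusted over the list alone. Lanosterol synthase Lss was at -1.04, Dhcr7 at -0.96 and the sterol sensor Insig1 at -0.70, and the list's median lay -0.37 from that of all genes (camera adjusted p = 8.25e-12, adjusted p = 0.198 with an estimated correlation). Of 23 lysosomal genes 9 fell, 15 adjusted over the list alone, such as the proteases Ctsd (-0.84) and Ctsb (-0.77) (camera adjusted p = 7.09e-08, adjusted p = 0.567 with an estimated correlation). Of 31 cell cycle genes 6 fell (2 to 6 over the 4 scalings), 12 adjusted over the list alone, led by Birc5, a spindle and survival protein, at -0.73 (camera adjusted p = 1.03e-04, adjusted p = 0.568 with an estimated correlation). The median of all genes between stimulated cells was -0.115, so these list-alone counts include a shift of all genes. Of 8 osteoclast genes 4 rose and 1 fell, 5 and 1 adjusted over the list alone (camera adjusted p = 1.10e-05, adjusted p = 0.202 with an estimated correlation). Acp5 was at 1.41 and Mmp9 at 1.27, while the bone collagen protease Ctsk changed by -0.72. Of 15 chemokines 2 rose and 2 fell, 3 and 4 adjusted over the list alone (camera adjusted p = 0.959), with Cxcl11 at 1.42 beside those above.

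Most classical effectors and all interferon genes did not pass between stimulated cells. Of 21 effectors 1 rose, the arginine-making enzyme Ass1 at 0.67, and 1 fell, the T cell ligand Tnfsf9 at -0.71, with 1 and 2 adjusted over the list alone (camera adjusted p = 0.0956). Of 37 interferon-stimulated genes 0 were called, also adjusted over the list alone (camera adjusted p = 0.0137, adjusted p = 0.794 with an estimated correlation). Il1b differed by 0.83 ± 0.23, Il6 by 0.51 ± 0.13, Nos2 by -0.06 ± 0.12 and Il10 by 0.09 ± 0.12, none past the threshold. Of 21 feedback regulators 5 fell and 2 rose, 6 and 2 adjusted over the list alone (camera adjusted p = 0.969), such as the phosphatase Dusp4 at -1.33 and the decoy kinase Irak3 at -0.89. Of genes called at rest 23 higher and 54 lower ones were called in the same direction with LPS, and 0 in opposite directions. Independent lists would share 0.596 and 4.38, but both comparisons use the same variance for each gene and are not independent. Across all genes tested, 50.3% of the differences had the same sign at both times.

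Limma called 722 genes between stimulated cells without the library labelled control replicate 2, 122 higher and 600 lower. With all 10 libraries it called 0, with 221 at an unadjusted p under 0.05. The excess of lower genes shrank under other scalings, which gave 327 higher and 397 lower with TMM, 247 and 305 with quantile normalization and 234 and 445 with rescaling. Leaving out depleted replicates 1, 2 or 3 without LPS gave 437, 358 or 363 genes, leaving out depleted replicates 2 or 3 with LPS gave 457 or 325, fitting only the 2 groups compared gave 56, the set number as a block 83 and only sets 2 and 3 gave 0.

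The difference between the 2 LPS responses asks directly whether GIV depletion changed the response. The median of all genes for this difference was -0.146. Counts of genes with a lower response adjusted over a list alone therefore include a shift of all genes. Tnfsf15 rose by 3.99 log2 units with LPS in depleted and by 1.51 in control cells, a difference of 2.48 ± 0.23 (SE, adjusted p = 0.0198). Ccl22 rose by 8.22 and 6.58, a difference of 1.64 ± 0.13 (adjusted p = 0.0112), and Il1a by 10.34 and 9.24, a difference of 1.09 ± 0.12 (adjusted p = 0.0281). Ccl7, listed at 0 in control cells without LPS, reached 128 TPM in the control library with LPS and 26.4 ± 0.835 TPM (SD, n = 3) in depleted cells, a difference on the log2 scale of TPM + 1 of -2.27 ± 0.14 (SE, adjusted p = 0.00525). Il33 is listed at 0 without LPS in all libraries. With LPS it was at 16.8 ± 2.84 TPM (SD, n = 3) in depleted cells against 2.70 TPM in the control library (difference 2.25 ± 0.25). The model pools the spread over the groups, and libraries listed at 0 add none. The SE of Il33, and in part that of Ccl7, may therefore be too small, here and between stimulated cells, and their p-values too favourable. Csf1r fell further in depleted cells, by -3.21 against -2.19 (difference -1.02 ± 0.12, adjusted p = 0.0355), as did the lipid desaturase Scd2, by -3.75 against -2.79 (difference -0.95 ± 0.10, adjusted p = 0.0281).

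Of 21 cholesterol biosynthesis genes 1, Lss at -1.03, was called for this difference over all genes, and 20 had a lower response in depleted cells adjusted over the list alone (camera adjusted p = 1.03e-11, adjusted p = 0.133 with an estimated correlation). Of 31 cell cycle genes 0 were called and 15 fell more adjusted over the list alone (camera adjusted p = 3.20e-06, adjusted p = 0.535 with an estimated correlation). Of 37 interferon-stimulated genes 0 were called, also adjusted over the list alone, and their median lay 0.31 above that of all genes (camera adjusted p = 6.14e-08, adjusted p = 0.535 with an estimated correlation). Of 14 matrix protease and remodelling genes 0 were called, with 3 higher and 1 lower adjusted over the list alone (camera adjusted p = 9.50e-04, adjusted p = 0.133 with an estimated correlation). Tnf, with a difference of -0.79 ± 0.11 (adjusted p = 0.0510), Il1b with 0.65 ± 0.30, Il6 with 0.53 ± 0.17 and Nos2 with -0.13 ± 0.15 did not pass.

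**Figure D4:**
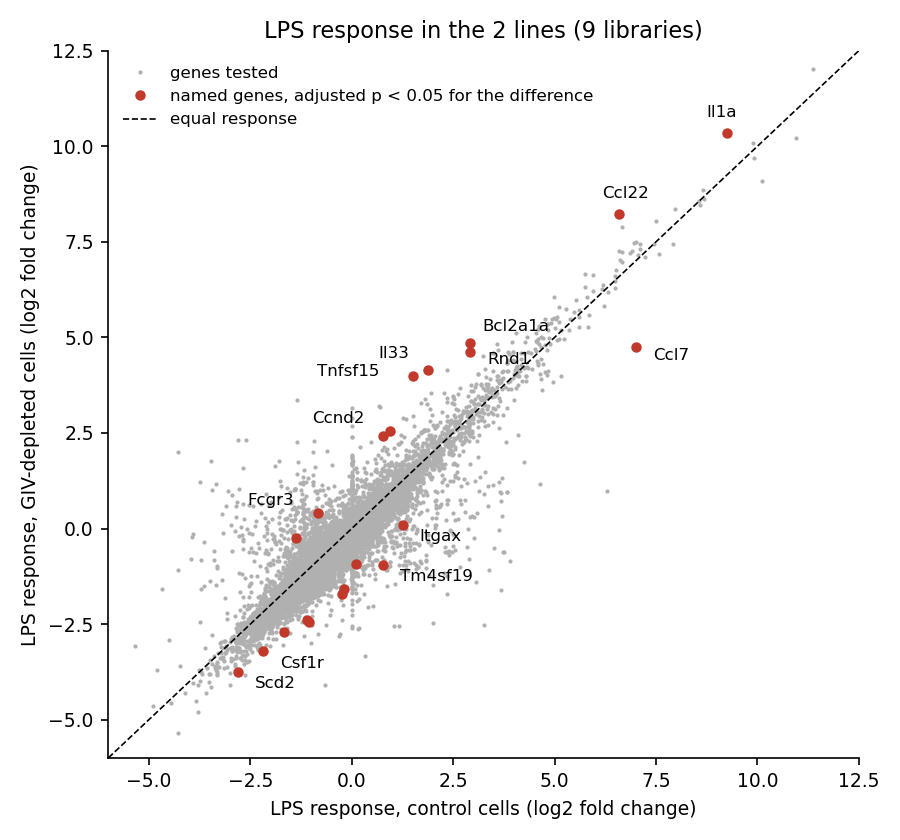
Log2 change with LPS in control cells (horizontal axis) and GIV-depleted cells (vertical axis) for the 13711 genes tested with 9 libraries, with the equal response dashed and 21 named genes that passed the test of the difference in red. Csf1r lies below the line at -2.19 and -3.21, and Ccl22 above it at 6.58 and 8.22.

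Limma called 31 genes for this difference without the library labelled control replicate 2, 13 higher and 18 lower. With all 10 libraries it called 0, with 226 at an unadjusted p under 0.05. Fcgr3 then had the opposite sign, at -0.14, but lay above the median of all genes of -0.80. TMM scaling gave 47 higher and 35 lower, quantile normalization 26 and 14, and removing each library's GC trend 39 and 154, sharing 26, 23 and 31 genes with the 31. No filter gave 9 and 27, the stricter filter 16 and 57, a pseudocount of 0.1 gave 7 and 23, robust variances 17 and 37, and variances without a trend 14 and 9. The set number as a block ended every call (0 genes), and only sets 2 and 3 gave 1. Without control replicate 1 there were 11, without depleted replicates 1, 2 and 3 at rest 10, 2 and 2, and without depleted replicates 1, 2 and 3 with LPS 0, 0 and 9.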

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

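The tests written after their result was seen were those on a common squeezing factor and on loss of short transcripts for the library apart, and the tests on scaling for the excess of lower genes and for the osteoclast list.

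The test of the difference between the 2 LPS responses, in the 9-library fit, picked out 21 named genes whose response differed between lines. No gene was called with the set number as a block, or without depleted replicate 1 or 2 with LPS. The response was higher in depleted cells for Tnfsf15 by 2.48, Il33 by 2.25, Bcl2a1a by 1.94, Rnd1 by 1.69, Ccnd2 by 1.66, Ccl22 by 1.64, the stress gene Ddit4 by 1.62, Fcgr3 by 1.22, the actin-binding Enc1 by 1.12 and Il1a by 1.09 log2 units. It was lower for Ccl7 (-2.27), Tm4sf19 (-1.71), Bhlhe41 (-1.46), Lhfpl2 (-1.40), the lysosomal Gpr137b (-1.40), the inhibitory receptor Sirpa (-1.28), Itgax (-1.16), Atp6v0d2 (-1.04), Lss (-1.03), Csf1r (-1.02) and Scd2 (-0.95). With all 10 libraries limma called 0 of all genes (226 at an unadjusted p under 0.05). The median of all genes was then -0.80, so a lower sign there is in part fixed by a shift of all genes. Signs were the same for 20 of the 21, and Fcgr3 was at -0.14, above that median.

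The library labelled control replicate 2 without LPS stood apart from the other control libraries. A common factor from its abundant small and ribosomal RNA would leave the ratios between coding genes in place. The spread of its TMM-scaled differences was 6.81 times that between the other 2 controls, which argues against a common factor as the whole cause. Loss of short transcripts is a candidate explanation, since its difference from the other controls rose with transcript length (Spearman 0.481 across genes, which are not independent replicates, against at most 0.184 in other libraries). Genomic DNA also stays open, with 42.3% of 1457 receptor genes of the olfactory and vomeronasal families above 0 against at most 37.3% in the others, although unknown depth could also move this share. Il1b and Il6 are listed at 0 in it, and no biological explanation was tested.

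More genes were lower than higher in depleted cells with LPS. Composition and scaling stay open, since protein-coding genes held 81.5% of the TPM of the lone control library with LPS and 76.8%, 76.7% and 73.9% of that of the depleted ones, and the 6 most abundant small and ribosomal RNA genes 10.4% against 15.2%, 15.6% and 18.1%. TMM scaling gave 54.8% lower among those called, from 83.1%, but it centres the genes, which fixes a near-even split, and rescaling, which does not centre them, gave 65.5%. With each library's GC trend removed 82.2% were lower, but that step kept each library's mean. The median of all genes was -0.114 after it and -0.115 before, so it cannot decide on a GC trend. Of the 4 ways to choose the lone library, 1 gave as many genes (the real 722, the highest other 2), and 4 are too few for a share under 0.05, so a change in the depleted cells themselves also stays open.

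Of 8 genes of the osteoclast list 5 were higher in depleted cells without LPS and 3 were not called. With all 10 libraries 0 of 8 were called, and 4 were higher adjusted over the list alone. The list's median above that of all genes was 0.86 with 10 libraries and 0.86 with 9. It was 0.88 under quantile normalization, which unlike a factor per library can move genes apart, and 0.83 with the GC trend removed. Leaving out each of the 9 libraries gave 0.78 or more, but those with LPS do not enter this difference and could hardly move it. These values argue against scaling, a GC trend or a single library without LPS as the whole cause. A difference between the lines that arose apart from GIV, such as clonal selection, was not tested and stays open, since each hairpin is seen in a single line. With an estimated correlation the list had an adjusted p of 0.0988, so an effect of GIV on this programme is a hypothesis.

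Other splits were counted for LPS in depleted cells and for depletion without LPS, into 3 and 3 libraries, or 2 and 3 for the latter in the 9-library fit. For LPS in depleted cells 1 of 10 splits gave as many genes as the real 1, with 2236 against a highest other of 0 in the 10-library fit and 10349 against 1 in the 9-library fit. For depletion without LPS 1 of 10 reached the real 167 in the 9-library fit (highest other 14). In the 10-library fit the real count by limma was 0 (408 at an unadjusted p under 0.05), which all 10 splits reach whatever they hold (highest other 5), so that count decides nothing. Splits this few cannot give a share under 0.05.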

How the results depend on the processing

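Chosen after the result was seen were the 9-library fit as a reported result, all of its alternatives, and removal of the GC trend. In the 10-library fit, TMM scaling gave 3261 genes for LPS in control cells, 5078 for LPS in depleted cells, 40 for depletion with LPS and 5 for the difference, 6, 9 and 12 lists for the last 3 comparisons, and Ccdc88a at -0.38 without LPS. Quantile normalization gave 2660, 4793, 2 for depletion without LPS and 10 with LPS, 9, 7 and 11 lists, and Ccdc88a at -0.23. Rescaling gave 4381, 6401 and 19 with LPS, 5, 10 and 11 lists, and Ccdc88a at -0.48. The replicate block gave 304 genes for LPS in control cells and 5 lists for depletion with LPS. No filter gave 1 gene and 13 lists for depletion without LPS, 28 genes and 0 lists with LPS, and 4 genes for the difference. The stricter filter gave 1249 genes for LPS in depleted cells, and 6 and 6 lists for depletion without and with LPS. A pseudocount of 0.1 gave 1 gene for depletion without LPS, 0 lists with LPS and 2 for the difference. Only the 2 groups compared gave 160 and 10440 genes for LPS and 67 genes and 11 lists for depletion with LPS. Only sets 2 and 3 gave 135 and 316 genes for LPS, 0 lists for depletion with LPS and 1 for the difference. Lists past the threshold numbered 1, 1, 0, 0 and 0 over the 5 comparisons with an estimated correlation and 7, 7, 0, 0 and 0 with fry. Leaving out each library gave 303 to 8075 genes for LPS in control cells, 1076 to 10349 for LPS in depleted cells, 0 to 167 genes, 2 to 11 lists and Ccdc88a at -0.50 to 0.67 for depletion without LPS, 0 to 722 genes and 2 to 12 lists with LPS, and 0 to 31 genes and 2 to 7 lists for the difference, the highest counts of genes being without the library labelled control replicate 2. For LPS in control cells, leaving out depleted replicates 1, 2 and 3 at rest gave 311, 307 and 303. For LPS in depleted cells, leaving out depleted replicates 1, 2 and 3 at rest gave 1194, 1110 and 1081, and those with LPS 1127, 1127 and 1076. In the 9-library fit, TMM scaling gave 253 genes for depletion without LPS and 82 for the difference, rescaling 277 and 64, quantile normalization 306 for depletion without LPS, and robust variances 54 for the difference. Removing the GC trend gave 1172 genes for depletion with LPS, 193 genes and 11 lists for the difference, and Ccdc88a at -0.78 with LPS, then past the threshold. The stricter filter gave 73 genes and 12 lists for the difference. The block gave 58, 83 and 0 genes for depletion without and with LPS and the difference. Deviations from group means correlated at -0.0013 to 0.0972 in 7 same-number pairs, 0 of them above 0.1. The 14 other-number pairs lay at -0.0972 to 0.0362, so a weak effect of the set stays open. Only the 2 groups compared gave 2859, 16 and 56 genes for LPS in control cells and depletion without and with LPS. Only sets 2 and 3 gave 0 and 0 genes for depletion and 1 for the difference. Using all 10 libraries gave 481, 2236, 0, 0 and 0 genes (1801, 4162, 408, 221 and 226 at an unadjusted p under 0.05 by limma), 2, 3 and 4 lists for the last 3 comparisons, and Ccdc88a at 0.22 without LPS. Lists numbered 3, 4, 0, 0 and 0 with an estimated correlation, and fry gave 1 for depletion without LPS and 4 for the difference. Leaving out each library gave 58 to 167 genes for depletion without LPS, 325 to 953 with LPS, and 0 to 21 genes and 6 to 13 lists for the difference, 13 without control replicate 3 and 12 without depleted replicate 1 at rest. Of 10291 values of named genes under alternatives, 9047 kept direction and side of the threshold, 988 lost the call, 32 gained it, 202 moved and 22 reversed. The 22 all arose with all 10 libraries: for LPS in control cells Sdhd 0.53, Atp5c1 0.78, Sdhb 0.61, mt-Nd2 1.06, mt-Co3 1.30, mt-Nd4l 1.03, mt-Nd1 1.30, Sqle 0.35 and Hist1h2bc 0.48, for depletion without LPS Fcgr3 0.18, Igf1 0.26, Oasl2 0.020, Tnfsf9 0.51, Msr1 0.44, Cd36 0.23, Ctss 1.2, Fcgr1 0.12, Adgre1 0.44, Ctsl 0.76, Fth1 0.99 and Plau 0.36, and for the difference Fcgr3 -0.14. In the 10-library fit the medians of all genes were 0.21 for LPS in control cells, 0.64 for depletion without LPS and -0.80 for the difference. A reversed sign there can therefore be a shift of all genes. A test on read counts was not run because the table holds none. Leaving out the lone control library with LPS gives no value for the comparisons that need it.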

Other observations

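The values in this part are from the planned tests in the 9-library fit, which was chosen after the result was seen. Glycolysis genes moved both ways in control cells with LPS. Of 19 glycolysis genes 5 rose and 6 fell, also adjusted over the list alone (camera adjusted p = 0.389). Over the 4 scalings 5 to 9 rose and 2 to 9 fell, with medians between -0.33 and 0.36. The glycolytic activator Pfkfb3 was at 3.18, the glucose transporter Slc2a1 at 1.54 and Pdk1, a kinase that inhibits pyruvate dehydrogenase, at -2.23. Stress genes moved both ways. Of 19 genes of the unfolded protein and integrated stress response 10 rose and 6 fell (10 to 12 and 3 to 7 over the 4 scalings), 11 and 7 adjusted over the list alone, with the phosphatase subunit Ppp1r15a at 2.50 and the chaperone partner Sdf2l1 at -1.52 (camera adjusted p = 0.00462, adjusted p = 0.417 with an estimated correlation). Of 15 immediate early genes 9 rose and 4 fell, also adjusted over the list alone, with Ier3 at 3.65 and Fos at -1.26 (camera adjusted p = 8.41e-05, adjusted p = 0.389 with an estimated correlation).

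GIV belongs to a family with Ccdc88b and Ccdc88c and acts near trimeric G proteins, PI3K, Akt and actin. In control cells with LPS 7 of 26 genes of this group rose and 9 fell, 7 and 10 adjusted over the list alone, a balance that turned under another scaling (7 to 14 rose, 3 to 10 fell, medians between -0.07 and 0.57), with Ccdc88c at -1.84 and the actin gene Actg1 at 1.34 (camera adjusted p = 0.118). Between stimulated lines 3 fell and none rose, 5 adjusted over the list alone, among them the PI3K subunits Pik3cb (-1.15) and Pik3cg (-0.76) (camera adjusted p = 0.113). Of 14 p53 targets 4 fell there, 6 adjusted over the list alone, with Phlda3 at -0.86 (camera adjusted p = 0.113), and of 15 oxidative stress genes 3 fell, 4 adjusted over the list alone, with the haem oxygenase Hmox1 at -0.87 (camera adjusted p = 0.0247, adjusted p = 0.638 with an estimated correlation). Ddit4, an inhibitor of growth signalling, was 1.45 higher.

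Of the lists for other cell types, those for fibroblasts, epithelial and endothelial cells and lymphocytes had 0 tested members, and the neutrophil list had 1, S100a8, which rose by 2.36 in control and 2.94 in depleted cells with LPS. Across 13711 genes, which are not independent replicates, the depletion differences without and with LPS had a Pearson correlation of 0.0899 and a Spearman correlation of 0.162.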
